A study of Arabidopsis thaliana with 36 samples.

How the data were processed

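RNA of floral tissue was hybridised to 36 custom 4x44K Agilent arrays on 11 slides, with mutant and control RNA on the same array. In ap3-3 the mutant was in Cy5 in sets 1, 3 and 5 and in Cy3 in sets 2 and 4. In pi-1 the mutant was in Cy5 in sets 1 and 3 and in Cy3 in sets 2 and 4, and in ap3-1 it was in Cy5 in sets 1 and 2 and in Cy3 in set 3. The 3 experiments were on separate slides and share no control RNA. The set 5 arrays of ap3-3 are described as biological replicate 1 in one label and as set 5 in the channel names. They were counted as a replicate of their own because of the channel names. Their ratios correlated with those of set 1 at 0.364, 0.209 and 0.438 at the 3 stages. Other pairs of sets 1, 3 and 5 had 0.238 to 0.443. At day 0 the others were lower (0.318 and 0.261), so that the correlations do not settle which label is right.

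Per the file headers, the deposited scanner files were made by Agilent Feature Extraction 10.5.1.1, while the processing notes of the authors name version 9.5.3.1. The deposited files give the intensity of each spot and of its local background per channel, as medians over pixels. They hold no mean signal, so that the median signal was used where the plan named the mean. The deposited files also give the scanner's log ratio of red over green in log10 units, normalized by Agilent's software, and other columns with 0 or 1 quality marks per spot. The table deposited by the authors holds log10 ratios that equal the scanner's ratio, with the sign turned on arrays with the mutant in Cy3, on 100% of spots. It therefore gives mutant over control as the arrays are labelled. Equal values do not show that every label is right, and for an ap3-1 array the direction is not settled, as described below.

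Each array has 45210 spots, of which 1425 are controls. Probes for loci number 36953 and cover 28327 loci, of which 4940 have more than 1 probe, and 27785 were found in the gene reference table (assembly TAIR10.1), which was used for symbols and gene order alone. The array was designed on the ath1:Jan2004 annotation, and no genome sequence was used. Another 6049 probes for unannotated regions and 633 for gene predictions were tested apart from the loci. The median signal per array was 80.5 to 193 in red and 47 to 81 in green, over backgrounds of 30 to 37 and 17 to 27.5. No spot was saturated, and 0.0114% to 1.27% of spots were outliers by the scanner's marks and were left out.

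Analyses used R 4.3.3, limma 3.58.1 and the data.table package (1.17.8). Signals were corrected with normexp (offset 50) against the local background and normalized by loess within each array, with control spots at weight 0. Spots of the same probe were averaged (15 probes had more than 1 spot). A probe was tested in an experiment if it was well above background on at least 3 arrays of a stage in the mutant's or the control's channel, and the probe with the highest mean signal stood for its locus. This left 19662 genes in ap3-3, 20491 in pi-1 and 20314 in ap3-1. Where all signals of 1 genotype were not well above background, the fold is a lower bound. It was computed against the array's lowest signal well above background, or against the spot's own signal where that was higher.

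Normexp fitted to all spots was set before the files were read. On 11 of the 36 arrays, 2 to 62 spots with a very high local background raised the noise SD that normexp fitted to 19 to 1170, against 0.774 to 4.93 on the other 25 arrays. The median absolute deviation of the log2 ratios was then 0.00689 to 0.14 on these arrays, against 0.0896 to 0.179 on the others. When spots with a local background over 2 times the array's median in either channel were left out before the fit, the noise SD was 1.02 to 2.41 and the median absolute deviation 0.103 to 0.167 on the 11 arrays. These arrays were ap3-3 day 0 set 4, day 2.5 set 2 and day 5 sets 2 and 4, pi-1 day 0 sets 1 and 2, day 2.5 set 3 and day 5 sets 1 and 2, and ap3-1 whole inflorescences sets 1 and 2. The planned correction was kept for the values reported first, and the version without these spots was added after the data were seen.

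Each experiment was fitted with limma (lmFit and eBayes) on the log2 ratios of its arrays, with 1 mean per stage and a gene-specific dye effect shared by the stages. The dye effect was past the threshold for 5352 genes in ap3-3, 5419 in pi-1 and 492 in ap3-1. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Differences between stages, and between ap3-3 and pi-1 with all arrays of both in 1 fit, were tested as contrasts. These choices, the gene lists and the rule for named genes were made before the data were examined. The rule named AP3 and PI in each comparison, the 5 genes that rose and the 5 that fell most among those past the threshold with the same sign on every array, up to 4 members per list past the threshold, and for differences the 3 largest each way. Further list members, and the ap3-1 genes given without an array, were named by the same rule or to complete a count.

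The 18 gene lists were floral organ identity and meristem MADS-box genes with partners, carpel and ovule development, stamen and early anther regulators, tapetum and pollen wall, petal development and cuticle, previously described B-function targets, photosynthesis, meristem and organ boundary, cell cycle, jasmonate, auxin, cytokinin, gibberellin, heat shock, mature pollen markers, vasculature markers, epidermis and trichome markers, and the B-class genes. Lists share members, such as SHP1 and SHP2 in the identity and the carpel lists. Each was tested in each of 9 comparisons with camera (correlation 0.01) and adjusted over lists within a comparison. Lists with under 3 members tested were left out of the set tests. This applied to the B-class genes and, in ap3-3 and pi-1, to the mature pollen markers, of which 1 was tested and 0 passed the threshold in limma. Of 147 tests, 41 were past the threshold with camera, 4 with an estimated correlation, 23 with fry for a common direction and 45 with fry for change either way.

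The alternatives were no background correction, an offset of 16, Agilent's own ratios, the authors' table, median centring, scale normalization between arrays, no filter and a stricter filter on dim probes, and the mean of all probes per locus. Others were no dye effect, set or slide as a random block, each stage alone, a 2-fold minimum, an adjusted p of 0.01, sets 1 and 5 averaged, and leaving out each set in turn. Alternatives added after the data were seen were the correction without spots of high local background, and for ap3-1 the day 6 array of set 2 left out, turned in sign, or left out together with a segment of chromosome 3 or with those spots. Without set 3 of ap3-1 the dye effect cannot be fitted and was dropped.

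The method was tested on simulated data. With changes of 0.5 and 1 (log2) added to 100 genes each, 94% and 100% were recovered at the size of ap3-3, 99% and 100% at that of pi-1 and 39% and 90% at that of ap3-1. Of all calls, 5.37%, 5.69% and 3.01% were false, and 0 genes were called by limma at a stage left unchanged. The simulated changes came back at nearly full size, with mean estimates of 0.498, 0.507 and 0.484 for 0.5. On 11 of the real arrays the ratios were shrunk. These rates therefore describe the simulated data and may not hold for the real arrays.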

Results

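Transcript levels were compared on 36 two-colour Agilent arrays of Arabidopsis thaliana, each of which carried RNA of a mutant in one dye and RNA of its control in the other. AP3 (AT3G54340) and PI (AT5G20240) encode the MADS-box proteins of the B function, which specify petals and stamens. The floral induction system is a line (ap1 cal AP1-GR) that forms meristem-like tissue in place of flowers until dexamethasone sets off many flowers at once. In this system, the null mutant ap3-3 was compared with its heterozygote on 5 arrays at each of 3 times, which were day 0 without induction, day 2.5 (flower stages 3 to 4) and day 5 (stages 5 to 6). The null mutant pi-1 was compared with its heterozygote on 4 arrays at each of the same times. Plants of both null mutant experiments were grown at 20 °C. The temperature-sensitive mutant ap3-1 was compared with the wild type after a shift from 16 to 27 °C for 24 hours, on 3 arrays each at day 3 and day 6 of the system and in whole inflorescences with flowers up to stage 10. RNA was pooled from 20 to 25 plants per sample, or 25 to 30 for whole inflorescences. Over the arrays, the median spot signal was 2.61 to 5.98 times the local background in red and 1.96 to 4.37 times in green. Between 53.2% and 66.9% of spots were well above background in green and between 53.3% and 86.6% in red. The number of arrays limits the precision of every value.

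All ratios are log2 of mutant over control with the standard error (SE) of the limma fit, and n is the number of arrays. Genes past the threshold had a Benjamini-Hochberg adjusted p under 0.05. The genes named for the largest changes had the same direction on every array of their stage. On 11 arrays the background correction, fitted to all spots, shrank the ratios. Where leaving out spots with a high local background moved a count of changed genes by over 1.5 times, or took a gene list test across the threshold, both values are given. Leaving out these spots was chosen after the data were seen. Loess normalization sets the average ratio of each array near 0, so that every change is relative to the other genes on the array. With median centring in its place, the median of all genes moved by over 0.1 in several comparisons, most in pi-1 at day 0 (0.45).

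The first question was which transcripts depend on AP3 before and during flower formation. In uninduced ap3-3 tissue, AP3 was at -0.27 ± 0.131 (SE, n = 4) and PI at -0.10 ± 0.111 (n = 5), each with an adjusted p of 0.993. AP3 signals were low there, at log2 levels of 6.6 to 7.1 in the mutant and 6.5 to 8.0 in the control. In the mutant at day 2.5 they were 12.4 to 12.7. The mutant's signal in set 5 at day 0 was not well above background. The AP3 ratio at day 0 therefore says little about AP3 before induction. limma found 0 of 19662 genes past the threshold, and 722 had an unadjusted p under 0.05. No member of any list changed. Photosynthesis genes (31 tested, median 0.03, camera adjusted p = 0.0112), jasmonate genes (13 tested, median 0.06, 0.0327) and cell cycle genes (19 tested, median -0.04, 0.0112) shifted as sets, each with an adjusted p = 0.599 with an estimated correlation. The jasmonate set did not pass without spots of high local background (camera adjusted p = 0.086).

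At day 2.5, the gene that rose most in ap3-3 was AT3G46770, at 1.61 ± 0.226 (SE, n = 5, adjusted p = 0.00357). It was followed by CRC, a YABBY regulator of carpel and nectary development, at 1.34 ± 0.178 (n = 5, adjusted p = 0.00313). STK, a MADS-box gene of ovule identity, rose by 0.38 ± 0.064, the photoreceptor gene PHYA by 0.32 ± 0.057 and the transporter gene ABCC10 by 0.20 ± 0.0382. The largest falls were in the B3-domain gene REM22 (-2.62 ± 0.209, adjusted p = 2.53e-05) and in SUP, which bounds the stamen whorl (-1.68 ± 0.236, adjusted p = 0.00357). RBE, a zinc finger gene of petal development, fell by 1.57 ± 0.132 on the log2 scale, and the nuclease gene ENDO3 by 0.83 ± 0.0738. The control's signal was well above background on 2 of 5 arrays for STK and 4 of 5 for AT3G46770, and the mutant's on 4 of 5 for SUP. Other probes gave 0.0017 to 0.25 for STK and -0.35 for ENDO3. Both B-class genes fell, AP3 to -1.43 ± 0.118 (adjusted p = 2.63e-05) and PI to -0.79 ± 0.111 (adjusted p = 0.00357), lower on 5 of 5 arrays each.

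Of 23 carpel and ovule genes tested at day 2.5 in ap3-3, CRC and STK rose and none fell. Adjusted over the list alone, 10 rose, and the set was higher (median 0.10, camera adjusted p = 5.04e-15, adjusted p = 0.00621 with an estimated correlation). With spots of high local background left out, 8 members rose, among them HEC2 (0.89 ± 0.11), HEC1 (0.79 ± 0.148) and SHP1 (0.78 ± 0.105). Of 20 floral organ identity genes, STK rose and SUP fell (camera adjusted p = 0.0279, adjusted p = 0.231 with an estimated correlation). RBE was the single change among 14 petal genes, SUP the single change among 5 previously described B-function targets, and both fell among 17 meristem and boundary genes (camera adjusted p = 0.929, 0.733 and 0.244). Leaving out the spots took the meristem and boundary set across the threshold (camera adjusted p = 0.0493, adjusted p = 0.322 with an estimated correlation), and 1 auxin gene then rose and 1 tapetum gene fell. The petal genes and the B-function targets had medians above 0 (0.01 and 0.04) and means below 0 (-0.11 and -0.29). Among the lists with 0 genes past the threshold, jasmonate (median -0.11, camera adjusted p = 0.0279) and photosynthesis genes (median -0.06, 0.0387) were lower and 9 gibberellin genes higher (median 0.03, 0.0279), with adjusted p = 0.588, 0.606 and 0.417 with an estimated correlation.

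In all, 32 of 19662 genes changed in ap3-3 at day 2.5, 5 higher and 27 lower, of which 6 changed by at least 2-fold. The number was 4 with median centring and 0 with scale normalization. In the fit without spots of high local background, 74 changed (34 higher, 40 lower), 31 of them shared with the 32. The count was 19 without set 1 and 8 without set 4 or without set 5.

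At day 5, CRC rose most in ap3-3, by 1.71 ± 0.178 (SE, n = 5, adjusted p = 0.000121), followed by AT3G46770 (1.58 ± 0.226). HEC1, a bHLH gene of carpel tip development, rose 2.14-fold (SE of the log2 ratio 0.176), AT4G26280 by 1.07 ± 0.134 and SHP1, a MADS-box gene of carpels and fruit, by 1.02 ± 0.152. AT5G09780 fell most, by 2.92 ± 0.351 on the log2 scale (adjusted p = 0.000389). REM22 fell by 2.70 ± 0.241 (n = 4), and SPL, which starts the formation of spore mother cells, by 2.14 ± 0.249 (n = 5), with the mutant's signal well above background on 2 of 5 arrays. The mutant's signal for AT5G09780 and the control's for SHP1 were so on 4 of 5. The 2 other probes for SPL gave smaller falls (means of -1.36 and -0.79, against -2.18), and other probes gave 0.55 for HEC1 and 0.22 for SHP2 as the lowest. AP3 was at -1.63 ± 0.118 and PI at -1.48 ± 0.111, each lower on 5 of 5 arrays with adjusted p = 4.52e-06.

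The carpel and ovule genes stood out at day 5 in ap3-3. Of 23, 11 rose and 1 fell, with 13 and 2 adjusted over the list alone (median 0.21, camera adjusted p = 8.26e-11, adjusted p = 0.0214 with an estimated correlation). They included SHP2 (0.92 ± 0.151), HEC2 (0.90 ± 0.147), SPT (0.40 ± 0.0403) and, as the one that fell, NGA4 (-0.31 ± 0.0562). Among 20 floral organ identity genes, SHP1, SHP2 and SEP4 (0.46 ± 0.0855) rose and the set was higher (camera adjusted p = 0.000281, adjusted p = 0.0214 with an estimated correlation, which was 0.0585 without spots of high local background, where 3 members rose and 2 fell). Among 16 stamen genes, SPL and the glutaredoxin gene ROXY1 (-0.42 ± 0.0617) fell, and 1 rose and 4 fell without those spots (camera adjusted p = 0.0305, adjusted p = 0.267 with an estimated correlation). RBE fell to -0.97 ± 0.132 and the wax gene CER1 rose to 0.22 ± 0.0502 among 14 petal genes, a set with a median of 0.03, a mean of -0.03 and a camera adjusted p of 0.529. Of 17 meristem and boundary genes, STM rose (0.32 ± 0.0434) and RBE fell, the median was 0.06 and the mean -0.03 (camera adjusted p = 0.0635), and 7 rose and 2 fell adjusted over the list alone. Without those spots 4 of them rose and 2 fell over all genes (camera adjusted p = 0.186).

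Smaller changes in ap3-3 at day 5 touched some of the remaining lists. CYCD3;2 fell by 0.30 ± 0.0476 on the log2 scale among 19 cell cycle genes (median -0.05, camera adjusted p = 0.0181, adjusted p = 0.418 with an estimated correlation). The gibberellin oxidase gene ATGA2OX1 rose by 0.36 ± 0.0768 among 9 gibberellin genes (camera adjusted p = 0.0304, adjusted p = 0.296 with an estimated correlation). The auxin response genes MP (0.28 ± 0.0659) and ETT (0.19 ± 0.0398) rose, higher on 5 and 4 of 5 arrays (camera adjusted p = 0.0635 for 12 auxin genes, and 0.0354 without spots of high local background, with adjusted p = 0.217 and 0.0992 with an estimated correlation). VSP1 rose by 0.46 ± 0.104 among 13 jasmonate genes, whose median was -0.02 and mean 0.06 (camera adjusted p = 0.529). MYB0, the trichome regulator also called GL1, fell by 0.34 ± 0.0792 among 5 epidermis genes (camera adjusted p = 0.529). None of the 31 photosynthesis, 6 tapetum, 6 heat shock, 5 cytokinin or 5 vasculature genes passed the threshold, and 1 heat shock gene and 1 B-function target fell without those spots.

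In total, 293 genes changed in ap3-3 at day 5, 113 higher and 180 lower, with 12 by at least 2-fold, against 8 genes with median centring and 68 with scale normalization. Without spots of high local background, 672 changed (281 higher, 391 lower), including the same 293, and SUP then fell to -1.32 ± 0.198 and SPL to -3.04. The count was 128 without set 1, 169 without set 2, 187 without set 3 and 70 without set 5. Between day 0 and day 5, 33 genes differed in their ratio, 10 higher and 23 lower at day 5. These included CRC (1.68 ± 0.25), AT4G26280 (1.09), CYP78A7 (0.62), AT5G09780 (-2.93), REM22 (-2.79 ± 0.316), SPL (-2.17), AP3 (-1.36 ± 0.175) and PI (-1.38 ± 0.156). For AP3 the day 0 ratio rests on low signals, so that its difference between stages cannot be read as a change in dependence. The number was 0 with median centring, 4 with scale normalization and 139 without spots of high local background, and the count was 9 without set 1 or set 2, 18 without set 3, 57 without set 4 and 4 without set 5.

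**Figure D1:**
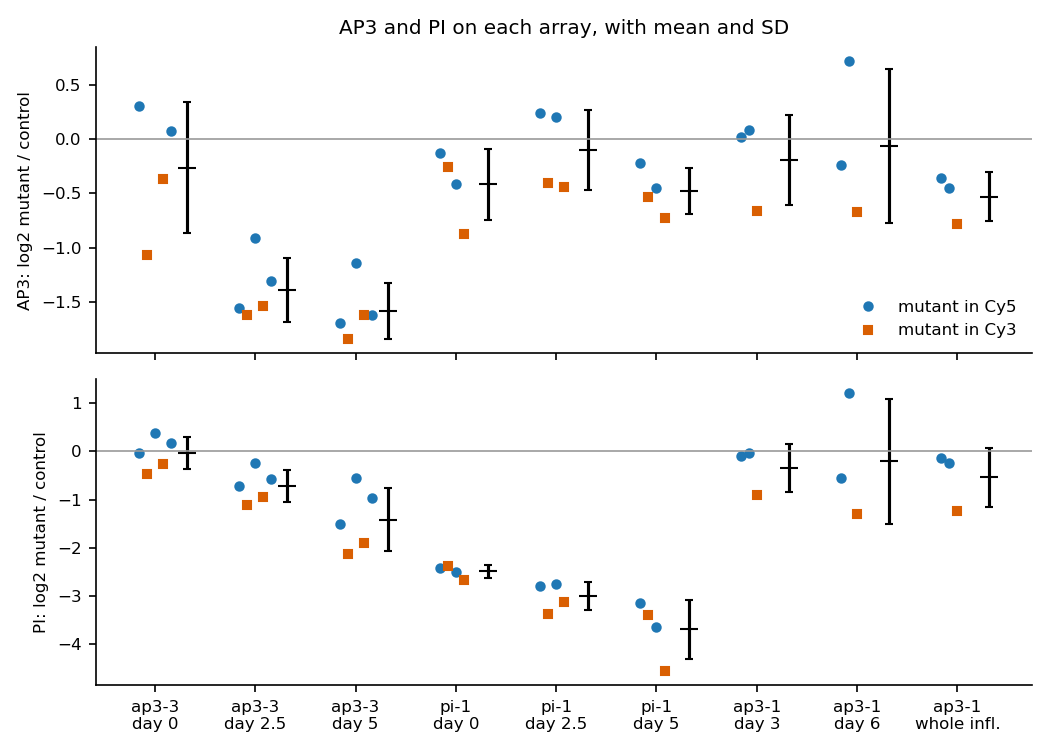
Log2 ratio of mutant over control for AP3 (top) and PI (bottom) on each of the 36 arrays in 9 groups. Circles mark the mutant in Cy5, squares the mutant in Cy3, and black dashes with bars the mean and SD of a group. PI in pi-1 at day 5 lay between -4.56 and -3.15, while in ap3-1 at day 6 it lay between -1.30 and 1.22.

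The matching question for PI was addressed with pi-1. In uninduced pi-1 tissue, PI itself was the single gene past the threshold, at -2.49 ± 0.145 (SE, n = 4, adjusted p = 7.28e-06, lower on 4 of 4 arrays). AP3 was at -0.42 ± 0.0886 (n = 4, adjusted p = 1), and without spots of high local background it fell to -0.51 with an adjusted p of 0.045, as the other gene of 2. Of the other lists no member passed the threshold. As sets, photosynthesis genes were higher (32 tested, median 0.06, camera adjusted p = 0.000264), and carpel and ovule genes (median -0.02, 0.000264), petal genes (-0.04, 0.00103), jasmonate genes (14 tested, -0.06, 0.00115) and floral organ identity genes (-0.01, 0.00673) were lower. With an estimated correlation, these lists had adjusted p = 0.444, 0.209, 0.444, 0.556 and 0.16. The identity set did not pass in camera without spots of high local background (camera adjusted p = 0.16).

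At day 2.5, AT3G46770 rose most in pi-1, by 2.43 ± 0.0994 (SE, n = 4, adjusted p = 4.74e-08). CRC rose by 1.59 ± 0.127, SHP1 by 1.45 ± 0.108, HEC1 by 1.25 ± 0.102 and INO, a YABBY gene of the outer integument of the ovule, by 1.23 ± 0.116. REM22 fell most, to -3.24 ± 0.114 (adjusted p = 4.74e-08), then PI to -3.01 ± 0.145 (1.41e-07), SUP to -2.26 ± 0.0991 (5.63e-08), RBE to -1.48 ± 0.0844 (6.92e-07) and AT2G02795 to -1.39 ± 0.173 (0.00131), with the mutant's signal well above background on 3 of 4 arrays. Other probes were as low as 0.94 for SHP1, 0.39 for HEC1, 0.24 for INO and for SHP2 and 0.0061 for TT16. AP3 was at -0.10 ± 0.0886 with an adjusted p of 0.826.

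Of 23 carpel and ovule genes at day 2.5 in pi-1, 9 rose and none fell, with 14 and 2 adjusted over the list alone (median 0.18, camera adjusted p = 1.88e-16, adjusted p = 0.00804 with an estimated correlation). SHP1, SHP2 (0.77 ± 0.0943) and TT16 (0.45 ± 0.0798) rose and SUP fell among 20 floral organ identity genes (camera adjusted p = 0.00546, adjusted p = 0.0573 with an estimated correlation, 0.0441 without spots of high local background). GA20OX2, an enzyme gene of gibberellin synthesis, rose by 0.40 ± 0.0636 and ATGA2OX1, an enzyme gene of gibberellin breakdown, by 0.42 ± 0.087 among 9 gibberellin genes (median 0.09, camera adjusted p = 0.000387, adjusted p = 0.0591 with an estimated correlation). The cytokinin oxidase gene CKX3 fell to -0.40 ± 0.0623 among 5 cytokinin genes (median -0.07, camera adjusted p = 0.0253). None of 5 vasculature genes passed the threshold, 1 rose adjusted over the list alone, and the set was higher (median 0.11, camera adjusted p = 0.0253). Cytokinin and vasculature genes each had adjusted p = 0.435 with an estimated correlation.

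Single members changed in other lists of pi-1 at day 2.5, none with a camera adjusted p under 0.05. TFL1, which keeps shoot meristems from becoming flowers, rose by 0.61 ± 0.105 while SUP and RBE fell among 17 meristem and boundary genes (median 0.04, mean -0.17). The cutin gene GPAT6 (-0.33 ± 0.049) and RBE fell among 14 petal genes (median 0.01, mean -0.09). ROXY1 (-0.38 ± 0.0802) fell among 16 stamen genes, AT2G31210 (-0.34 ± 0.0403, other probes -0.20 and -0.08) among 8 tapetum genes (median 0.01, mean -0.04) and SUP among 5 B-function targets (median 0.04, mean -0.40). TAA1, of auxin synthesis, rose by 0.20 ± 0.0406. In all, 199 of 20491 genes changed, 78 higher and 121 lower, 13 of them by at least 2-fold. Median centring gave 6 and scale normalization 107. The count was 93 without set 1, 117 without set 2 and 79 without set 3 or without set 4.

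At day 5, AT4G26280 (1.67 ± 0.139) and AT3G46770 (1.67 ± 0.0994) rose most in pi-1 (SE, n = 4), followed by CRC (1.34 ± 0.127), SHP2 (1.22 ± 0.0943) and SHP1 (1.17 ± 0.108). AT5G09780 fell most, to -4.42 ± 0.172 (adjusted p = 1.87e-08), followed by PI (-3.69 ± 0.145, adjusted p = 1.87e-08). SPL was at -3.29 ± 0.203, AT2G02795 at -2.38 ± 0.173, with the mutant's signal well above background on 2 of 4 arrays, and REM22 at -2.20 ± 0.114. The 2 other probes for SPL gave -2.08 and -1.45, and the lowest value of another probe was 0.76 for SHP1 and 0.69 for SHP2. AP3 fell by 0.48 ± 0.0886 on the log2 scale (adjusted p = 0.00919, lower on 4 of 4 arrays).

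Of 23 carpel and ovule genes at day 5 in pi-1, 11 rose and 1, NGA4 (-0.37 ± 0.0824), fell, with 14 and 4 adjusted over the list alone (median 0.24, camera adjusted p = 7.82e-08, adjusted p = 0.0795 with an estimated correlation, which was 0.022 without spots of high local background). Of 16 stamen genes, SPL, ROXY1 (-0.48 ± 0.0802), MYB26 (-0.32 ± 0.0781) and TPD1, a signal for tapetum formation (-0.61 ± 0.0725), fell and NUB (0.33 ± 0.0807) rose (median -0.11, camera adjusted p = 0.000111, adjusted p = 0.277 with an estimated correlation). All 19 cell cycle genes lay below 0, and CYCD3;1 (-0.25 ± 0.0481), CDKB1;1 (-0.21 ± 0.0532) and CYCD3;2 (-0.19 ± 0.0353) fell (median -0.10, camera adjusted p = 4.29e-07, adjusted p = 0.129 with an estimated correlation). The cytokinin genes ARR7 (0.34 ± 0.0593) and CKX3 (0.31 ± 0.0623) rose among 5 (median 0.28, camera adjusted p = 0.000638, adjusted p = 0.274 with an estimated correlation). GAPB (0.25 ± 0.0375) and RBCS1A (0.19 ± 0.0462), of carbon fixation, rose among 32 photosynthesis genes (median 0.07, camera adjusted p = 0.000638, adjusted p = 0.353 with an estimated correlation). The jasmonate synthesis genes LOX2 (0.57 ± 0.093) and AOC1 (0.31 ± 0.0481) rose among 14 (median 0.12, camera adjusted p = 0.0315, adjusted p = 0.561 with an estimated correlation), a set that did not pass without spots of high local background (camera adjusted p = 0.0513).

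Other genes at day 5 in pi-1 changed within lists of mixed direction. WUS, which maintains the stem cells of the meristem, fell to -0.71 ± 0.15, SUP to -0.71 ± 0.0991 and RBE to -1.15 ± 0.0844, while LAS (0.40 ± 0.0631), STM (0.28 ± 0.0505) and KNAT2 (0.21 ± 0.0479) rose among 17 meristem and boundary genes (median 0.09, mean -0.05, camera adjusted p = 0.423). RBE and PTL (-0.25 ± 0.0533) fell among 14 petal genes (camera adjusted p = 0.066). MYB0 fell to -0.49 ± 0.0698 among 5 epidermis genes (median -0.10, camera adjusted p = 0.0488, 0.0691 without spots of high local background, adjusted p = 0.277 with an estimated correlation). SHP1, SHP2 and AGL8 (0.21 ± 0.0485, higher on 2 of 4 arrays) rose and SUP fell among 20 floral organ identity genes (camera adjusted p = 0.0832). GNC (0.36 ± 0.0619) rose and SUP fell among 5 B-function targets (median 0.09, mean -0.01, camera adjusted p = 0.423). None of 12 auxin, 9 gibberellin, 8 tapetum, 6 heat shock or 5 vasculature genes passed the threshold, and 1 gibberellin gene rose without those spots.

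In total, 685 of 20491 genes changed in pi-1 at day 5, 372 higher and 313 lower, with 25 by at least 2-fold. Only 12 passed with median centring and 323 with scale normalization. The count was 450 without set 1, 446 without set 2, 206 without set 3 and 249 without set 4. Between day 0 and day 5, 131 genes differed in their ratio, 48 higher and 83 lower at day 5. Among them were AT4G26280 (1.63), AT3G46770 (1.62), CRC (1.34), AT5G09780 (-4.24 ± 0.243), SPL (-3.19), AT2G02795 (-2.33) and PI (-1.20 ± 0.205). AP3 differed by -0.06 ± 0.125 (adjusted p = 0.997), and by 0.03 without spots of high local background. The count was 1 with median centring, 72 without set 1, 42 without set 3 and 68 without set 4.

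Whether both null mutants change the same genes was tested on the 19514 genes tested in both. At day 5, 192 genes changed the same way, 67 higher and 125 lower, and 0 changed in opposite directions, against 2.15 and 2.87 for independent lists. Without spots of high local background, 332 did (127 higher, 205 lower), against 6.01 and 7.49. The shared count was 6 with median centring, 54 with scale normalization, 98 without ap3-3 set 1, 92 without ap3-3 set 2, 63 without ap3-3 set 5 and 121 without pi-1 set 3. At day 2.5, 20 genes changed the same way (3 higher, 17 lower), and 48 did without spots of high local background. Across genes, which are not independent replicates, the ratios had a Pearson r of 0.644 (Spearman 0.439) at day 5, 0.35 (0.107) at day 2.5 and -0.0782 (-0.101) at day 0.

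**Figure D2:**
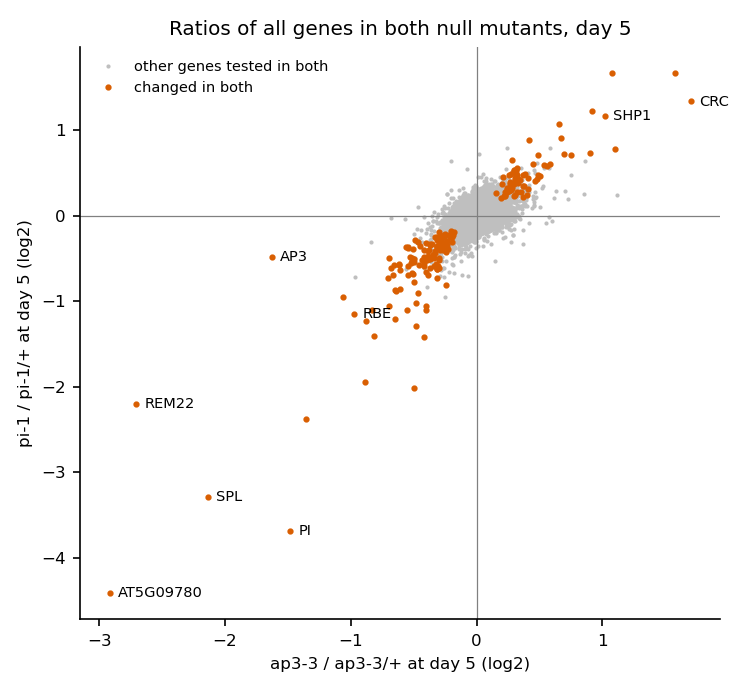
Log2 ratios of ap3-3 (x axis) and pi-1 (y axis) at day 5 for the genes tested in both, with the 192 genes that changed the same way in orange. CRC and SHP1 lie above 0 in both, and AT5G09780, SPL and REM22 below -2 in both.

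The difference between the null mutants was tested directly. PI was less reduced in ap3-3 than in pi-1, by 2.23 ± 0.194 (SE) at day 2.5 and 2.21 ± 0.194 at day 5 (adjusted p = 6.26e-07 and 7.35e-07). AP3 was lower in ap3-3 by -1.33 ± 0.164 (adjusted p = 0.000361) and -1.15 ± 0.164 (0.00424). These were the 2 genes past the threshold of 20639 at day 2.5, and AT1G30170 (1.51 ± 0.251, adjusted p = 0.0223) was the other of 3 at day 5. PI lay between -1.11 and -0.24 on the ap3-3 arrays at day 2.5 and between -3.37 and -2.76 on those of pi-1, and the ranges did not overlap at day 5 either (-2.13 to -0.56 and -4.56 to -3.15). Each mutant was on several slides of its own. The fit had no slide term and took every array as independent, so that variation between slides enters the SE only in part. With slide as a random block, the estimated correlation within slides was 0.0314 in this fit. Differences between the slides of both experiments cannot be told apart from the mutant. At day 5, 8 genes differed without spots of high local background, and scale normalization turned PI at day 5 to -1.78, an array with shrunken ratios having been stretched. The day 5 count was 5, 7 and 1 without ap3-3 set 1, 2 and 5, and 6 without pi-1 set 1 or set 2.

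**Figure D3:**
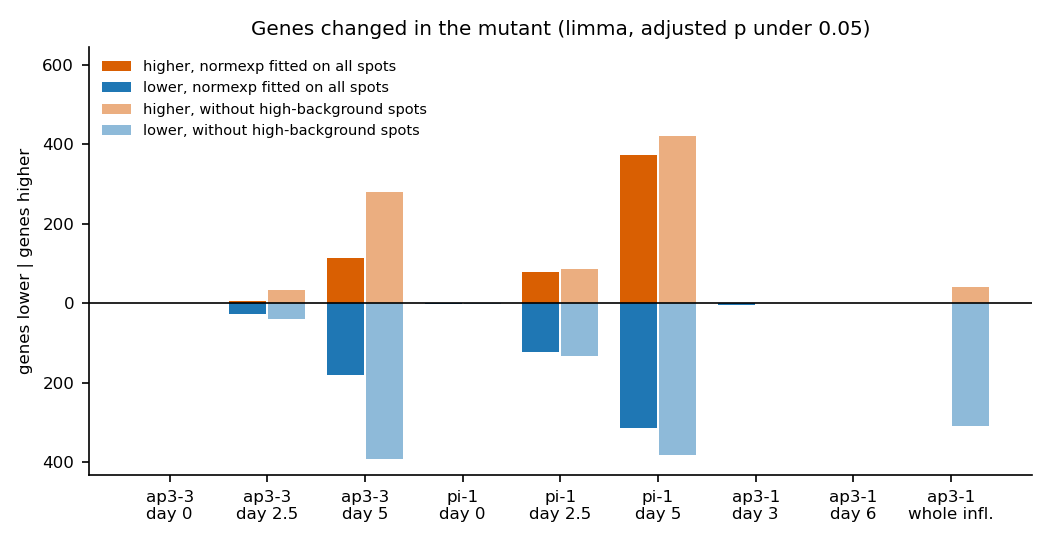
Number of genes higher (up, orange) and lower (down, blue) in the mutant per comparison at an adjusted p under 0.05. Dark bars show the background correction fitted to all spots, and pale bars the correction without spots of high local background. In pi-1 the dark bars go from 1 gene at day 0 to 685 at day 5.

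The third experiment compared ap3-1 with the wild type after 24 hours at 27 °C. No array compared them without the shift. A response to the shift can therefore not be told apart from differences between the lines that were there before it. The direction of 1 of its arrays, set 2 at day 6, is not settled. Its ratios correlated at -0.593 to -0.30 across genes with the other arrays of ap3-1 in the floral induction system, although its labels give the dye orientation of sets 1 and 2. The ap3-1 counts, AP3 and PI are therefore given as labelled, without this array and with its sign turned, both chosen after the data were seen. Gene lists are given as labelled, with the other values where these cross the threshold.

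At day 3, MYB0 rose in ap3-1 by 1.31 ± 0.0877 (SE, n = 3, adjusted p = 0.00663, higher on 3 of 3 arrays). AT3G07470 (-0.96 ± 0.101), XT1 (-0.93 ± 0.092), the cytochrome P450 gene CYP71B22 (-0.90 ± 0.0902) and the cell wall gene EXGT-A3 (-0.75 ± 0.0726) fell, and the 2 probes for XT1 disagreed. AP3 was at -0.30 ± 0.164 (adjusted p = 0.448), a fitted value with the dye effect removed that has 2 of 3 arrays above 0, and PI at -0.54 ± 0.281 (adjusted p = 0.428). These 5 genes were the ones past the threshold of 20314, and 2958 had an unadjusted p under 0.05. MYB0 was the only one left without spots of high local background.

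Without the set 2 array of day 6, 728 genes changed at day 3 (372 higher, 356 lower), and 869 with its sign turned. The largest rises were then AT3G16180 (6.13 ± 0.205), AT3G26890 (5.08 ± 0.2), AT3G27025 (4.98 ± 0.247, n = 2), AT3G28220 (4.82 ± 0.151) and AT3G13940 (4.41 ± 0.144). The largest falls were MEE59 (-4.65 ± 0.116), AT2G13665 (-4.44 ± 0.234), AT3G26050 (-4.20 ± 0.147), UNE16 (-4.10 ± 0.0803) and AT3G16750, which was at least 15.9-fold lower, with 0 of 3 mutant signals above background. The dimmer signal was well above background on 1 of 3 arrays for AT3G16180, AT3G26890 and AT3G26050 and on 2 of 3 for AT2G13665. PI fell to -0.49 ± 0.0746 (adjusted p = 0.0114) and AP3 was at -0.28 ± 0.0785 (adjusted p = 0.116). With the sign turned, PI was at -0.48 and AP3 at -0.28. Without set 2 as a whole, 172 genes changed, and without set 1, 0 did.

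Carpel and ovule genes at day 3 in ap3-1 had 0 of 23 members past the threshold over all genes, and 8 rose adjusted over the list alone (median 0.22, camera adjusted p = 0.000134, adjusted p = 0.224 with an estimated correlation). Without the doubtful array, CRC rose (1.47 ± 0.163, adjusted p = 0.00247), as did NGA3 (0.45), and HEC2 was at least 1.47-fold higher. Of 14 petal genes, 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00219, adjusted p = 0.469 with an estimated correlation). Without that array, SHN1 (1.05) and GPAT6 (0.87), both of the cuticle, and TCP5 (0.49) rose and RBE (-1.02 ± 0.129) fell. Auxin genes (12 tested, median 0.27, camera adjusted p = 0.000317) and photosynthesis genes (33 tested, 0.16, 0.00219) were higher as sets, with adjusted p = 0.126 and 0.506 with an estimated correlation. Jasmonate (median -0.36, camera adjusted p = 0.00241) and vasculature genes (-0.18, 0.0304) were lower, with adjusted p = 0.49 and 0.469 with an estimated correlation. The vasculature set did not pass without the doubtful array (camera adjusted p = 0.06) or with its sign turned (camera adjusted p = 0.0561), and the gibberellin set, with a camera adjusted p of 0.0938 as labelled and 0.0653 with the sign turned, passed without it (median 0.20, camera adjusted p = 0.0455, adjusted p = 0.494 with an estimated correlation). Of 5 epidermis genes, MYB0 rose (camera adjusted p = 0.00495, adjusted p = 0.469 with an estimated correlation). Without the doubtful array, IAA19 (0.56), GA20OX1 (0.56) and RGL2 (0.47) also rose, and AOS (-0.46) and CYCB1;1 (-0.92) fell.

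At day 6, limma found 0 of 20314 genes past the threshold in ap3-1 as labelled, and 354 had an unadjusted p under 0.05. AP3 was at -0.18 ± 0.164 and PI at -0.40 ± 0.281 (SE, n = 3, adjusted p = 1 each). No list member passed, and photosynthesis genes were lower as a set (median -0.11, camera adjusted p = 1.19e-05, adjusted p = 0.771 with an estimated correlation). This set depends on the doubtful array, with a median of -0.0068 without it (camera adjusted p = 0.974) and 0.12 with its sign turned (camera adjusted p = 0.0318, adjusted p = 0.861 with an estimated correlation). Without the doubtful array, 243 genes changed (116 higher, 127 lower), and 509 with its sign turned. Then PI fell to -0.92 ± 0.0894 (n = 2, adjusted p = 0.00175), SPL to -1.86 ± 0.152, the jasmonate synthesis gene AOC1 to -2.23 ± 0.162 and the mitotic cyclin gene CYCB1;1 to -1.03 ± 0.0789, and AP3 was at -0.45 ± 0.094 (adjusted p = 0.0795). With the sign turned, PI was at -0.87 and AP3 at -0.46. The jasmonate set was lower without the array (median -0.26, camera adjusted p = 0.00457, adjusted p = 0.778 with an estimated correlation) and with its sign turned (median -0.29, camera adjusted p = 0.000239, adjusted p = 0.544 with an estimated correlation), and at -0.06 as labelled (camera adjusted p = 0.775). AT3G16180 was at least 60.2-fold and AT3G26890 at least 25.9-fold higher, and AT2G13665 at least 18.1-fold, AT3G26050 at least 14.9-fold and AT3G16750 at least 12.9-fold lower. AT3G27025 (5.07), AT3G13940 (4.29), AT3G28220 (4.20), MEE59 (-4.50, with the mutant's signal above background on 1 of 2 arrays) and UNE16 (-3.79) completed the largest changes. Without set 2 as a whole, 123 genes changed.

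Many of these genes lie next to each other on chromosome 3. Without the doubtful array, 205 of 1423 tested genes (14.4%) between AT3G12600 and AT3G30390 changed at day 3, against 518 of 18689 (2.77%) elsewhere. MYB0, CYP71B22, AOC1 and IAA19 (AT3G15540) lie in this segment, as do the genes named above with codes from AT3G13940 to AT3G28220. Without the doubtful array, IAA19 and MYB0 were the only auxin and epidermis members past the threshold at day 3. AOC1 was the only jasmonate member past it at day 6. CYCB1;1 (AT4G37490) lies on chromosome 4 near MEE59 (AT4G37300) and CYP81F4 (AT4G37410), which have large ratios in the same line, so that its fall cannot be read as a change of the cell cycle. At day 6 the counts were 110 (7.73%) and 132 (0.706%), with a p of 9.59e-62 in Fisher's exact test (2-sided). Neighbouring genes are not independent in this test. In whole inflorescences, 0 of the 1423 genes changed in limma without that array, against 5 elsewhere, and 38 (2.67%) against 413 (2.21%) when spots of high local background were left out as well (Fisher's exact test, p = 0.264). With these genes left out as well, 433 genes changed at day 3 and 112 at day 6. Neighbouring genes on chromosome 4, such as CYCB1;1 and MEE59, stay in these counts.

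**Figure D4:**
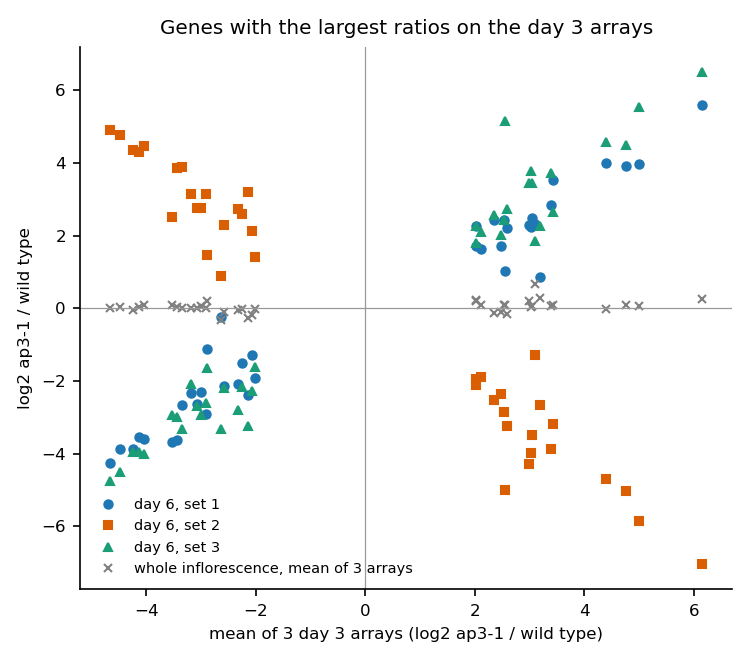
Log2 ratio of 39 marker genes in ap3-1, with the mean of the 3 day 3 arrays on the x axis and, on the y axis, day 6 set 1, set 2, set 3 and the mean of whole inflorescences. Set 2 has a slope of -1.05, and in whole inflorescences the highest slope of an array is 0.0284.

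In whole inflorescences of ap3-1, DDB1B (3.73 ± 0.289, SE, n = 3) and AGD9 (2.14-fold, SE of the log2 ratio 0.0907) rose, each on 3 of 3 arrays with adjusted p = 0.0166, and 1674 genes had an unadjusted p under 0.05. AP3 was at -0.64 ± 0.164 (adjusted p = 0.32) and PI at -0.73 ± 0.281 (adjusted p = 0.527), lower on 3 of 3 arrays. Of 16 tapetum and pollen wall genes, 0 passed over all genes in limma and 13 fell adjusted over the list alone (median -0.67, camera adjusted p = 1.1e-15, adjusted p = 0.262 with an estimated correlation). All 5 mature pollen markers fell adjusted over the list alone (median -0.65, camera adjusted p = 1.3e-08, adjusted p = 0.262 with an estimated correlation). Stamen genes were lower (16 tested, 2 fell adjusted over the list alone, median -0.12, camera adjusted p = 0.00666, adjusted p = 0.327 with an estimated correlation). None of the 8 heat shock genes passed (median -0.11, camera adjusted p = 0.315). Auxin genes were just short of the threshold as a set (camera adjusted p = 0.0508, and 0.0483 without spots of high local background, with adjusted p = 0.262 and 0.378 with an estimated correlation).

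Without spots of high local background, 348 genes changed in whole inflorescences in place of 2, 40 higher and 308 lower, with 78 by at least 2-fold. DDB1B rose by 4.22 ± 0.102, AT3G49270 by 1.91, AGD9 2.14-fold, and the anthocyanin genes DFR and MYB90 by 1.60 and 1.09. AT3G28980 fell to -2.24, AT3G23840 to -1.75, AT5G62750 to -1.71, ERD6 to -1.64 and AT2G20142 to -1.60. The pollen genes VGD1 (-1.17 ± 0.187), STP11 (-0.99 ± 0.0945), AGP11 (-0.82 ± 0.085) and AGP6 (-0.58 ± 0.0684) fell, 4 of 5 mature pollen markers (median -0.82, camera adjusted p = 5.76e-11, adjusted p = 0.0156 with an estimated correlation, which was 0.0665 without the doubtful array). QRT3, which separates pollen grains (-1.55 ± 0.222), AT2G31220 (-0.76), LAP6 (-0.55), MYB26 (-0.68 ± 0.0905) and the gibberellin synthesis gene GA3OX1 (-0.72 ± 0.121) also fell. Without the doubtful array as well, 453 genes changed, among them AP3 (-0.60 ± 0.0772, adjusted p = 0.00896) and PI (-0.67 ± 0.0774, adjusted p = 0.00607). All arrays of whole inflorescences were on the same slide, and sets 1 and 2 were among those with shrunken ratios. In set 1, 86.6% of red spots were well above background, against 63.0% in set 2 and 66.8% in set 3. The 348 genes were not counted again with each set left out.

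With all spots, 5 genes changed in whole inflorescences without the doubtful array and 15 with its sign turned. The 5 were DDB1B (3.74), AGD9 (1.09), JAL23 (1.05), UBP21 (0.97) and MYC3 (0.80). UBP21 (AT5G46740), AGD9 (AT5G46750) and MYC3 (AT5G46760) are neighbours by their codes. Whether their rises are separate responses was not tested. AP3 was then at -0.62 and PI at -0.69, and with the sign turned at -0.62 and -0.68. The count was 69 without set 1 and 0 without set 2 or set 3. Between day 3 and day 6, limma found 0 genes with a different ratio as labelled and 818 at an unadjusted p under 0.05, with AP3 at 0.13 ± 0.228 and PI at 0.13 ± 0.39. Without the doubtful array 2 genes differed, AT5G09780 (-3.49 ± 0.181) and CYP81F4 (-1.80 ± 0.167), AP3 turned to -0.18 and PI to -0.43, and with the sign turned 4 genes differed.

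Across genes, ap3-1 as labelled had a low correlation with the null mutants. Pearson's r was 0.0134 and 0.0146 between ap3-1 at day 6 and ap3-3 and pi-1 at day 5, 0.13 for pi-1 without the doubtful array, and 0.113 and 0.176 with its sign turned. It was 0.0605 and 0.116 between ap3-1 at day 3 and ap3-3 and pi-1 at day 2.5, and 0.136 and 0.178 between whole inflorescences and ap3-3 and pi-1 at day 5. The share of changed genes near the mutated locus was compared with that elsewhere in the null mutants, and no difference passed the threshold. Within 2 Mb of AP3, 16 tested genes changed in ap3-3 at day 5 (1.82%, against 1.48% elsewhere, Fisher's exact test, 2-sided, p = 0.393), and within 2 Mb of PI, 29 changed in pi-1 (3.55% against 3.35%, p = 0.766). In ap3-1 without the doubtful array, the share within 2 Mb of AP3 was below that elsewhere, 2.57% against 3.64% at day 3 (Fisher's exact test, p = 0.0979) and 0.112% against 1.25% at day 6 (p = 0.000404), where the chromosome 3 segment counts as elsewhere.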

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

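The tests of the array labelled ap3-1 day 6 set 2 and of the chromosome 3 genes were chosen after the pattern was seen, except the comparison with further probes. The tests of shared targets in ap3-1 and the counts over other splits of the arrays were written before their results were seen.

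The array labelled ap3-1 day 6 set 2 ran against the other ap3-1 arrays of the floral induction system. Over 39 marker genes chosen on the day 3 arrays, its ratios had a slope of -1.05 on theirs, and 0 of the 39 had the same sign. A bias of the dye orientation is argued against by the other arrays with the mutant in Cy5, the lowest slope of which was 0.829, and a failed hybridisation by the correlation of -0.978 across these genes. An exchange of mutant and control RNA or dyes on this array may account for the slope of -1.05, and whether it took place at labelling or in the records cannot be read from the files. No biological explanation was tested.

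Genes with large ratios in ap3-1 at days 3 and 6 were neighbours on chromosome 3, 20 of the 39 marker genes among them. The ap3-1 mutation itself is argued against by whole inflorescences, where the highest slope of an array on the marker genes was 0.0284. As these plants were outside the floral induction system, they cannot test sequence linked to ap3-1 in the lines of the system. A response to the lasting loss of AP3 or PI at 20 °C is argued against by the null mutants, where the highest slope was 0.0118. Of the marker genes, 36 were tested in ap3-3 and 31 in pi-1. The null mutants had no temperature shift, so that they cannot test a response to the shift or to a sudden loss of AP3. A candidate explanation is a genome segment that differs between the ap3-1 and control lines in the floral induction system, which stays open. The segment was drawn on the day 3 calls, and calls were again more frequent in it on the day 6 arrays of sets 1 and 3 (Fisher's exact test, p = 9.59e-62). This repeats the pattern in the same lines, with neighbouring genes that are not independent, and does not test its cause. Sequence differences under single probes cannot be told apart from such a segment. Only 2 marker genes had a further probe, and the quotients of further over used probe, with a median of 0.414, were 0.995 for UNE16, on chromosome 4, and -0.168 for AT3G28140, the single gene of chromosome 3 among them. The marker genes outside the segment, which it does not cover, lie on chromosomes 4 (9), 3 (4), 2 (3), 1 (2) and 5 (1). By their codes, those on chromosome 4 lie in AT4G00520 to AT4G01130, AT4G13640 to AT4G13950 and AT4G37300 to AT4G37410. Without the doubtful array, 4.37% of chromosome 4 genes changed at day 3, against 1.78% to 2.59% on chromosomes 1, 2 and 5. At day 6 the shares were 1.52% and 0.407% to 0.513%. Whether further segments differ between the lines was not tested.

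Genes that changed in both null mutants at day 5 were tested as a set for a move in the same direction in ap3-1 without the doubtful array. Of 182 such genes tested there, 127 had the same direction at day 3, 155 at day 6 and 140 in whole inflorescences (limma's rotation test fry, adjusted p = 0.0124, adjusted p = 0.00531 and adjusted p = 0.0124, before adjustment 0.0108, 0.00177 and 0.0124). At day 3 this rests on the 66 genes higher in the null mutants (median 0.16, fry alone 0.000229), as the 116 lower genes did not pass by themselves (median -0.11, 0.068). Across these genes, which are not independent replicates, the correlation with pi-1 was 0.401, 0.809 and 0.619. Loss of the same targets in ap3-1 is a candidate explanation, and as no technical explanation was tested for this pattern it stays a hypothesis. The values before adjustment without spots of high local background were 0.0015, 0.000293 and 0.000895.

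In 6 of 90 groups of 4 or 5 arrays, 1 array lay far from the others by Dixon's test, which by chance is passed in about 1 of 20 groups. At day 2.5 in ap3-3, set 3 gave 0.231 for CRC, against 1.41 to 1.82 on the other arrays, and -1.28 for REM22, against -3.11 to -2.79. At day 5 in pi-1, AT3G46770 was 1.45 in set 1 (others 1.73 to 1.75) and PTL -0.433 in set 3 (others -0.22 to -0.178), neither of which was far from the others without spots of high local background, where AT3G46770 in set 1 was 1.53. In set 4 of the same stage, TPD1 was -0.951 (others -0.512 to -0.479) and CDKB1;1 was -0.421 (others -0.151 to -0.133).

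The contrast of day 5 with day 0 found 33 genes in ap3-3, among them CRC at 1.68, AT4G26280 at 1.09, CYP78A7 at 0.62, AT5G09780 at -2.93, REM22 at -2.79, SPL at -2.17, AP3 at -1.36 (with low signals at day 0) and PI at -1.38. The same contrast found 131 genes in pi-1, among them AT4G26280 at 1.63, AT3G46770 at 1.62, CRC at 1.34, AT5G09780 at -4.24, SPL at -3.19, AT2G02795 at -2.33 and PI at -1.20. The null mutants differed in 2 genes at day 2.5, with PI at 2.23 and AP3 at -1.33, and in 3 at day 5, with PI at 2.21, AT1G30170 at 1.51 and AP3 at -1.15. Among probes for unannotated regions, 1 of 1110 was higher in pi-1 at day 2.5 and 3 at day 5, and among probes for gene predictions, 2 of 123 were lower in ap3-1 at day 3.

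Other splits, made by turning the sign of arrays or exchanging them between stages or mutants, were counted for each number of changed genes. For the day 5 contrast with day 0, the real split called the most genes in ap3-3 (33 genes, 1 of 100 splits with as many). Another split called 31, close to the real count. In pi-1 the real split also called the most genes (131 genes, 1 of 35 splits with as many, highest other 0). With 35 splits this makes chance unlikely but cannot exclude it. Between the null mutants at day 2.5, 4 of 100 splits had as many as the real 2 genes. As another split called 4, above the real count, chance is not excluded there. It is not excluded at day 5 either (3 genes, 6 of 100 splits, highest other 19). Why another split called 19 was not tested. Such counts do not test single genes such as PI. The other comparisons had too few splits for a share under 0.05. In ap3-3 the real counts and the highest others were 0 and 5 at day 0 (16 of 16 splits with as many), 32 and 1 at day 2.5 and 293 and 1 at day 5. In pi-1 they were 1 and 0, 199 and 0, and 685 and 1. In ap3-1 they were 5 and 0 at day 3, 2 and 0 in whole inflorescences, and 0 and 11 for day 6 against day 3 (10 of 10 splits). At day 6 the real count was 0 in limma (354 genes at an unadjusted p under 0.05) and the highest other 509, from the split that turns the set 2 array, which points to a structure of the arrays. They were, without spots of high local background, 74 and 1 at day 2.5 and 672 and 4 at day 5 in ap3-3, and 348 and 1 in whole inflorescences.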

How the results depend on the processing

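The settings without spots of high local background, without the day 6 set 2 array of ap3-1, with its sign turned and without the chromosome 3 segment were chosen after the results were seen. All others were planned. Over planned settings, the named genes gave 1036 values with the same direction and call. Another 383 kept the direction but no longer passed the threshold, 5 newly passed it and 15 reversed in direction. Over added settings these numbers were 148, 4, 12 and 7. The size of the ratios was not compared. Signals of 1.96 to 5.98 times the background limit the ratios of dim genes. Except where a cause is given, the cause was not tested.

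Comparisons are listed by mutant and stage, with the number of changed genes. Counts rose without background correction (ap3-3 day 2.5 to 71, day 5 to 635 and day 5 against day 0 to 137, pi-1 day 0 to 2, ap3-1 day 3 to 14 and whole inflorescences to 370, ap3-3 against pi-1 at day 5 to 5). With Agilent's own ratios they were 54, 617 and 109 in ap3-3, 3 in pi-1 at day 0, 103 in whole inflorescences, 2 for ap3-1 day 6 against day 3, and 4 and 1 for ap3-3 against pi-1 at days 2.5 and 5. With the deposited table they were 54, 616 and 113, then 3, 106, 2, 4 and 1. Without spots of high local background they were 74, 672 and 139 in ap3-3, 2 in pi-1 at day 0, 1 in ap3-1 at day 3, 348 in whole inflorescences and 8 for ap3-3 against pi-1 at day 5. An offset of 16 gave 12 in ap3-1 at day 3, 1 for day 6 against day 3 and 1 for ap3-3 against pi-1 at day 5.

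Median centring gave 4 and 8 in ap3-3 at days 2.5 and 5, and 0 for day 5 against day 0. It gave 0, 6, 12 and 1 in pi-1, and 0 at day 3 and 1 in whole inflorescences of ap3-1. For ap3-3 against pi-1 it gave 0 on both days. Under it, the median of all genes moved by -0.14 and -0.16 in ap3-3 at days 0 and 2.5. For day 5 against day 0 it moved by 0.22 in ap3-3. In pi-1 it moved by 0.45 at day 0 and by -0.31 in the contrast. In ap3-1 it moved by 0.23 at day 3, by 0.14 in whole inflorescences and by -0.20 in the contrast. In ap3-3 against pi-1 at day 2.5 it moved by -0.19. Scale normalization gave 0, 68 and 4 in ap3-3, 2 in pi-1 at day 0, 107 and 323 at days 2.5 and 5, 0 at day 3 and 87 in whole inflorescences of ap3-1, and 0 for ap3-3 against pi-1 on both days.

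Without a dye effect, counts were 176 in ap3-3 at day 5 and 19 for its contrast, 109, 366 and 68 in pi-1 at days 2.5, 5 and the contrast, 10 and 7 at day 3 and in whole inflorescences of ap3-1, 1 for its contrast and 1 for ap3-3 against pi-1 at day 2.5. Each stage fitted alone gave 19 and 57 in ap3-3 and 105 and 199 in pi-1, below the counts reported. It gave 853 at day 3 and 25 in whole inflorescences of ap3-1, above them. Sets 1 and 5 averaged, with fewer replicates, gave 17, 128 and 6 in ap3-3. With a 2-fold minimum counts were 6, 12 and 9 in ap3-3, 13, 25 and 21 in pi-1 and 1 in ap3-1 at day 3, and at an adjusted p of 0.01 they were 20, 116 and 5, then 90, 282 and 58, then 1 at day 3 and 0 in whole inflorescences, both by the stricter threshold.

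Residuals of arrays of the same set did not pair (median r -0.0174 in ap3-3, -0.11 in pi-1 and -0.197 in ap3-1, against 0.00556, 0.0452 and 0.101 for other sets). With set as a random block, 19 genes changed in ap3-1 at day 3, and the other counts stayed within 1.5 times of those reported.

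Without the day 6 set 2 array, ap3-1 gave 728 at day 3, 243 at day 6, 5 in whole inflorescences and 2 for the contrast. With its sign turned the counts were 869, 509, 15 and 4, without it and the chromosome 3 segment 433, 112, 6 and 2, and without it and spots of high local background 762, 272, 453 and 1.

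Genes changed the same way in both null mutants at day 5 numbered 9 with a 2-fold minimum, 118 without a dye effect, 316 without background correction, 293 with Agilent's ratios, 290 with the deposited table, 6 with median centring, 54 with scale normalization, 36 with stages fitted alone, 99 with sets 1 and 5 averaged and 332 without spots of high local background. The correlation of ap3-3 at day 5 with ap3-1 at day 6 was 0.113 with the sign turned, that of pi-1 0.176 with it turned and 0.13 without the array, with or without spots of high local background, and that of ap3-3 at day 2.5 with ap3-1 at day 3 was 0.0934 without a dye effect. The gene list tests past the threshold numbered 4 with an estimated correlation and 23 with fry.

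Leaving out 1 set at a time, counts ranged from 8 to 29 in ap3-3 at day 2.5, from 70 to 201 at day 5 and from 4 to 57 for the contrast, with the lowest values of all 3 without set 5. They ranged from 79 to 117, 206 to 450 and 42 to 90 in pi-1, lowest without set 3, with 79 at day 2.5 also without set 4. In ap3-1 they ranged from 0 to 172 at day 3, 0 to 123 at day 6 and 0 to 69 in whole inflorescences. The range was 1 to 7 for ap3-3 against pi-1 at day 5 and 63 to 165 for genes shared at day 5. Correlations of ap3-3 with pi-1 ranged from -0.161 to 0.0412 at day 0, 0.244 to 0.403 at day 2.5 and 0.55 to 0.664 at day 5. Those with ap3-1 at day 6 ranged from -0.152 to 0.0839 for ap3-3 and from -0.167 to 0.13 for pi-1, at day 3 from 0.0292 to 0.0869 and 0.0429 to 0.198, and in whole inflorescences from 0.00188 to 0.163 and 0.083 to 0.21. Without set 3 of ap3-1 no dye effect was fitted.

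Directions reversed for AP3 and PI as follows. AP3 in pi-1, day 5 against day 0, was 0.10 without background correction, 0.16 with Agilent's ratios and with the deposited table, 0.043 with scale normalization, 0.030 without spots of high local background and 0.0080 without replicate 2. In ap3-1 at day 3, AP3 was 0.033 with median centring and ranged from -0.33 without replicate 2 to 0.049 without replicate 3. At day 6 AP3 ranged from -0.45 without replicate 2 to 0.24 without replicate 3 (0.02 without replicate 1), and PI from -0.92 to 0.34 in the same way. For day 6 against day 3, AP3 was -0.16 with median centring, -0.13 without replicate 2, -0.18 without the doubtful array, with its sign turned, and without it and spots of high local background, and PI was -0.17, -0.42, -0.43, -0.39 and -0.43 under the same settings, with 0.31 for AP3 and 0.43 for PI without replicate 1. PI in ap3-3 against pi-1 at day 5 was -1.78 with scale normalization, which stretched an array with a median absolute deviation of 0.00689. The share of higher genes among those called moved from 15.6% to 45.1% in ap3-3 at day 2.5 and from 100% to 9.46% in whole inflorescences of ap3-1 without background correction.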
